A study of Mus musculus with 30 samples.

How the data were processed

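The starting material was the authors' deposited Cuffdiff tables, 1 for each condition, each with 48432 genes. Per the submitters' processing notes, reads were aligned with STAR to the mouse assembly mm10, and Cufflinks and Cuffdiff were then used for quantification; no version of any of these programs was stated. Per the file headers and the notes, the count columns deposited by the authors were taken to be expected counts of fragments for each gene in each library, and the FPKM columns deposited by the authors were read as Cuffdiff FPKM. No read was aligned again. Depth below means the sum of the deposited expected counts of a library, given in M fragments.

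Genes were tested on the deposited expected counts, rounded to whole numbers. Before rounding, 3.24% of the values of the control table were not whole, 3.13% in the LPS table, 3.08% in the IFNγ table, 3.18% in the IL4 table and 3.16% in the IL10 table. Each comparison was tested only within a single table, because values from different tables may not share a scale. The control libraries occur in all 5 tables, and 99.959% (LPS), 99.961% (IFNγ), 99.975% (IL4) and 99.976% (IL10) of their values lay within 0.5 fragments of those of the control table.

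Gene identifiers were matched to GENCODE vM21 for GRCm38/mm10. With the version number 40601 identifiers matched, a further 7450 matched without it and 381 were absent from the reference, and 62 symbols were held by more than 1 identifier. Symbols and positions were taken from that reference, which may differ from the annotation used by the authors. Cuffdiff gave a status other than OK to 57 genes in the control table, 73 in the LPS table, 97 in the IFNγ table, 65 in the IL4 table and 73 in the IL10 table, and these included some of the most abundant macrophage transcripts. Such genes are not named for the table concerned. They were also left out of the gene lists, a choice made after their values were seen; with them kept in the lists, 188 list tests passed in place of 186.

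The main test was the quasi-likelihood test of edgeR 4.0.16 on R 4.3.3, with filterByExpr and TMM scaling and with adjusted p under 0.05 by the Benjamini-Hochberg method within each comparison. A prior count of 2 was used for log2 CPM, not for log2 fold changes. Errors beside these are standard errors. Levels are CPM from edgeR with the TMM factors, as the mean with the standard deviation of 3 libraries. The filter left 14421 genes for the genotype comparison in control, 15036 for LPS, 14987 for IFNγ, 14967 for IL4 and 14974 for IL10. A difference between the genotypes' responses (interaction) was the interaction term of the same fit on the 12 libraries of both genotypes with and without that stimulus. Where a group had no fragments at all, the fold is given as a minimum with the empty group set to 3 fragments over its libraries. Where it had 1 to 3 fragments, the ratio carries an exact 95% counting interval; such minima and intervals cover counting error only.

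The genes to name were set by a rule fixed before the data were examined. For each genotype comparison and each stimulus in Lyz2cre, the 10 largest rises and the 10 largest falls were taken among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Non-overlap of 3 against 3 libraries happens by chance for 10% of unchanged genes. For each interaction the 5 largest in each direction were taken. Members of the gene lists were named besides.

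The gene lists were also fixed before the data were examined, 30 in all: HIF pathway components; glycolysis and glucose uptake; other hypoxia-response genes; NF-kB inflammatory genes; type I interferon-stimulated genes; GBP and IRG GTPases; MHC class II presentation; MHC class I presentation, IL-4-induced macrophage genes, IL-10-induced macrophage genes, arginine and nitric oxide metabolism, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cholesterol biosynthesis, cell cycle, unfolded protein and integrated stress response, NRF2 antioxidant genes, lysosome and phagosome, macrophage identity, neutrophil and granulocyte markers, monocyte markers, dendritic cell markers, B cell markers, T and NK cell markers, mast cell, basophil and eosinophil markers, erythroid and megakaryocyte markers, stromal and fibroblast markers, endothelial markers, sex-linked genes and ribosomal protein genes. Lists with at least 4 members past the filter were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Their p-values were adjusted by the Benjamini-Hochberg method over all lists and comparisons together. The same test was repeated with the correlation estimated from the data, and with fry.

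The alternatives tried were relative log expression (RLE) size factors, no filter on low counts, only the 6 libraries of the groups compared, the Wald test of DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with FPKM of at least 1 in 3 libraries, a single fit of all 30 libraries, genes of status other than OK left out, only changes of at least 2-fold, each library left out in turn, and the replicate numbers as a block. After the values had been seen, 2 more were added: without the libraries that stood apart, which were Lyz2cre_control replicate 1 for the most genes detected and Hif1aKO_IL10 replicate 3 for the highest share of ribosomal RNA, and with genes of status other than OK kept in the lists. Scripts were run with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

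The steps were tried on simulated counts with known changes. For the genotype comparisons, 80% of the 1.5-fold and 93% of the 2-fold changes were recovered in control, 72% and 88% in LPS, 72% and 92% in IFNγ, 82% and 91% in IL4, and 70% and 90% in IL10. For the stimuli in Lyz2cre these were 80.8% and 91.9% for LPS, 82% and 92% for IFNγ, 73% and 97% for IL4, and 76% and 87% for IL10. For the interactions they were 70% and 76% for LPS, 60% and 79.8% for IFNγ, 68% and 77% for IL4, and 53% and 76% for IL10. Between 2.8% and 9.7% of the calls in a simulation were false.

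The labels do not tie any library to a mouse, so p-values measure only the spread between these samples. A correlation of residuals showed no pairing by replicate number, from -0.08 to 0.09 over 60 pairs within a genotype and from -0.1 to 0.11 over 75 pairs across genotypes. Counts for genes with near-identical copies, such as histone genes, Rpl29 with its pseudogenes, and the Gbp, Serpina3, Ifit, Ms4a4, Pilr and Akr1c families, are less certain, and so are the low values of Gapdh and Lyz2. Exon-level counts, splicing and transcript forms lie outside what gene totals can give, and nothing was compared between stimuli or between interactions, which share control libraries.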

Results

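RNA from 30 cultures of mouse bone marrow-derived macrophages was sequenced as single-end reads of 100 nt, with 3 libraries in each of 10 groups. The marrow came from C57BL/6 mice of 10 weeks that carried Lyz2cre alone or together with floxed Hif1a alleles, and the groups of the second kind are called libraries labelled Hif1aKO throughout. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1. Cells of both genotypes were left untreated (control) or were given LPS at 100 ng/ml or IFNγ, IL-4 or IL-10 at 10 ng/ml for 18 h. Comparisons of genotypes within a condition addressed what differed between libraries labelled Hif1aKO and Lyz2cre libraries in that condition. Comparisons of each stimulus with control addressed the response of each genotype, and interactions addressed whether the responses of the genotypes differed.

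Depth ran from 23.5 M fragments in Lyz2cre_control replicate 2 to 38.7 M in Lyz2cre_IFNgamma replicate 1, with a median of 29.5 M. Groups separated by stimulus on the first component, which held 44.6% of the variance of 15667 genes, and on the second with 21.4%. The fifth component, with 4.5%, separated the genotypes in all conditions. The biological coefficient of variation of edgeR was 6.03% over all groups, lowest in Hif1aKO_IFNgamma (3.69%) and highest in Hif1aKO_IL10 (11.3%). Between libraries of the same group the chi-square per degree of freedom ran from 2.69 to 44.9 over 30 pairs, so no library was a copy of another. Lyz2cre_control replicate 1 had the most genes detected (22602), and Hif1aKO_IL10 replicate 3 had the highest share of ribosomal RNA (0.195%).

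**Figure D1:**
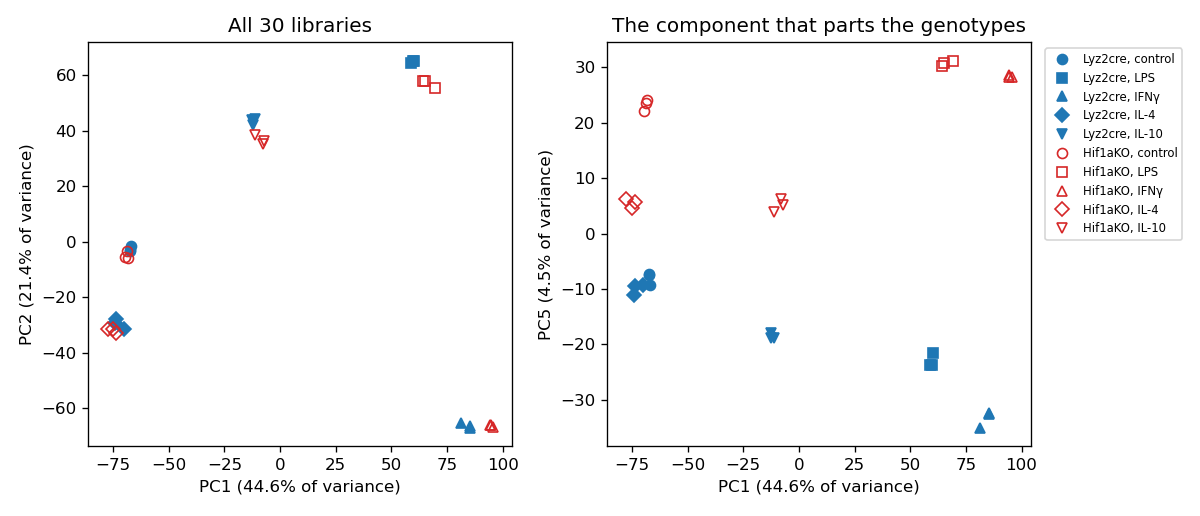
Principal components of log2 CPM for all 30 libraries, component 1 against component 2 (left) and component 1 against component 5 (right). Each point is 1 library, and colour and shape give condition and genotype.

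Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530) was counted in every library, and at every condition its level in CPM was higher in the 3 libraries labelled Hif1aKO than in the 3 Lyz2cre libraries. In control its level was 258, 253 and 309 CPM in replicates 1 to 3 labelled Hif1aKO and 239, 222 and 225 CPM in Lyz2cre. With LPS it was 2470, 3010 and 2640 CPM against 1460, 1410 and 1450 CPM, and with IFNγ 933, 937 and 964 CPM against 677, 619 and 697 CPM. With IL-4 it was 236, 250 and 236 CPM against 196, 213 and 206 CPM, and with IL-10 1770, 1620 and 1750 CPM against 1090, 1040 and 1010 CPM. The log2 fold change between genotypes was 0.26 ± 0.07 in control (adjusted p = 0.0465), 0.91 ± 0.07 in LPS (2.14e-08), 0.51 ± 0.06 in IFNγ (1.92e-05), 0.23 ± 0.06 in IL4 (0.0181) and 0.71 ± 0.07 in IL10 (3.46e-06), by edgeR. In Lyz2cre libraries Hif1a rose with LPS (2.77), IFNγ (1.69) and IL-10 (2.24), whereas with IL-4 its change of -0.12 did not pass (adjusted p = 0.118). The response was larger in libraries labelled Hif1aKO for LPS, by 0.65 (adjusted p = 0.000183), and for IL-10, by 0.45 (0.0151), while differences of 0.24 for IFNγ (0.165) and -0.03 for IL-4 (0.955) did not pass. The call in control was lost with RLE size factors (adjusted p = 0.0505), on log2(FPKM + 0.1) (0.0502) and without any 1 of 4 libraries (0.0553 to 0.163). In IL4 it was lost without Lyz2cre_IL4 replicate 1 (adjusted p = 0.116) or Hif1aKO_IL4 replicate 2 (0.112), and for the response to IL-10 without Hif1aKO_control replicate 1 (0.0595). The difference in response to IFNγ passed without a filter on low counts (adjusted p = 0.0203) and without Hif1aKO_control replicate 3. Gene totals do not say which exons the fragments came from, so the deletion could not be checked with them.

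**Figure D2:**
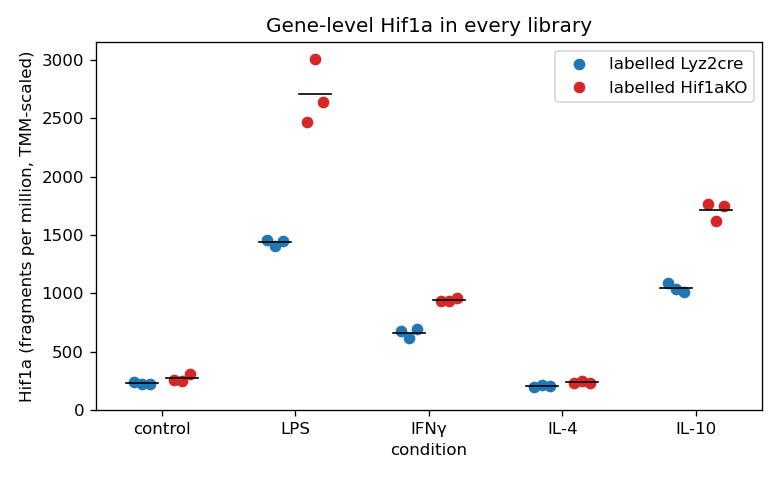
Hif1a in CPM in each of the 30 libraries by condition and genotype. Each point is 1 library and the black line is the mean of 3.

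In untreated macrophages the lists with the lowest camera p were cell cycle genes, 12 of 35 higher in libraries labelled Hif1aKO (median log2 fold change 0.46), neutrophil markers, 9 of 13 lower (-0.94), and glycolysis genes, 15 of 22 lower (-0.38). Of all lists tested only cell cycle genes kept the call with an estimated correlation (adjusted p = 0.0279), while neutrophil markers (adjusted p = 0.0937) and glycolysis genes (adjusted p = 0.239) lost it. Ankrd37, a hypoxia-inducible gene, stood at 1.44 ± 0.299 CPM against 12.2 ± 1.17 CPM in Lyz2cre (mean and standard deviation, n = 3), a log2 fold change of -3.07 ± 0.15, and the aldolase gene Aldoc at 8.74 against 23.7 CPM (-1.44 ± 0.08). The lactate exporter gene Slc16a3 stood at 21.7 against 55.5 CPM (-1.35 ± 0.08). Arg1, which encodes arginase 1, was 5.16-fold higher at 13.7 ± 1.01 against 2.62 ± 0.524 CPM, and the integrin gene Itgax was higher by 1.35 ± 0.08.

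Of 14421 genes tested with edgeR, 1098 differed between the genotypes in control, 626 of them higher and 472 lower in libraries labelled Hif1aKO. Among the highest by the rule were Rpl29 (7.84 ± 0.24, 16.8 against 0.0747 CPM, adjusted p = 4.89e-09), Lrrc14b (4.76 ± 0.19), Arg1 (2.37 ± 0.13), Gdf3 (1.82 ± 0.07) and the beta-galactosidase gene Glb1 (1.68 ± 0.05, 111 against 34.7 CPM). Others among them were Igha (1.61 ± 0.26), Atrnl1 (1.6 ± 0.07), the histone gene Hist1h4b (1.38 ± 0.13) and Akr1c12 (1.38 ± 0.18). The largest falls were those of the peptide transporter gene Slc15a2 (-3.63 ± 0.22, 0.557 against 6.98 CPM), Ankrd37, the small RNA gene Rny3 (-2.11 ± 0.52), the granule protein gene Camp (-2.03 ± 0.09, 4.56 against 18.7 CPM) and Narf (-1.84 ± 0.05, 18.8 against 67.5 CPM). They were followed by Rgs11 (-1.81 ± 0.14), Ccrl2 (-1.69 ± 0.07), Rny1 (-1.68 ± 0.43), the caveolin gene Cav1 (-1.57 ± 0.11) and Aldoc. Rny3 and Rny1 rested mostly on a single Lyz2cre library, with standard deviations of 38.5 and 17.3 CPM there, and both calls were lost with DESeq2 (adjusted p = 0.0664 and 0.0929). That of Igha was lost on log2(FPKM + 0.1) (0.0603).

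Of 22 glycolysis genes, 0 were higher, 15 were lower and 7 did not pass, with 1 higher and 15 lower when adjusted over the list alone. The camera adjusted p was 8.08e-11, and the call was lost at adjusted p = 0.239 with an estimated correlation. Of 26 other hypoxia-response genes 1 was higher, 9 were lower and 16 did not pass (2 and 11 adjusted over the list alone; camera adjusted p = 7.72e-06), but adjusted p = 0.0704 with an estimated correlation. Ak4 (-2.33 ± 0.26), P4ha2 (-0.8 ± 0.13) and the mitophagy gene Bnip3 (-0.74 ± 0.07) were among the lower ones. The HIF pathway list had 2 higher, 2 lower and 4 that did not pass (2 and 2 adjusted over the list alone, adjusted p = 0.647), with the prolyl hydroxylase genes Egln3 (-1.23 ± 0.14) and Egln1 (-0.3 ± 0.05) lower and Epas1 higher (0.36 ± 0.06).

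Cell cycle genes had 12 of 35 higher, 0 lower and 23 that did not pass (22 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.6e-11). Ccna2 (0.79 ± 0.14), Birc5 (0.76 ± 0.2) and Rrm2 (0.68 ± 0.13) were among them, and the list kept adjusted p = 0.0279 with an estimated correlation. Neutrophil markers had 1 higher, 9 lower and 3 that did not pass of 13 (1 and 11 adjusted over the list alone; camera adjusted p = 2.63e-11). Camp, Mpo (-1.71 ± 0.18), Prtn3 (-1.29 ± 0.27) and Ngp (-1.21 ± 0.08) were lower, and the list gave adjusted p = 0.0937 with an estimated correlation. Cholesterol biosynthesis genes were lower in 12 of 23, higher in 0, and 11 did not pass (15 lower and 0 higher adjusted over the list alone; camera adjusted p = 1.41e-08). Hsd17b7 (-0.48 ± 0.1) and Stard4 (-0.41 ± 0.08) were lower, and the list gave adjusted p = 0.156 with an estimated correlation.

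Type I interferon-stimulated genes were lower in 12 of 25, higher in 0, and 13 did not pass (18 lower, 0 higher adjusted over the list alone), among them Ifit3 (-0.73 ± 0.11), Ifit1 (-0.67 ± 0.12) and Isg15 (-0.55 ± 0.09). Their camera adjusted p was 1.24e-08, but adjusted p = 0.373 with an estimated correlation. MHC class II genes had 6 of 11 higher, 0 lower and 5 that did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.00281). H2-Eb1 was higher by 0.5 ± 0.06, and the list gave adjusted p = 0.393 with an estimated correlation. NRF2 antioxidant genes had 7 of 16 lower, 0 higher and 9 that did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.000217). Nqo1 was lower (-0.79 ± 0.14), and the list gave adjusted p = 0.239 with an estimated correlation. IL-10-induced genes had 3 higher, 1 lower and 17 that did not pass of 21 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0197). Il1rn was higher by 1.14 ± 0.08, and the list gave adjusted p = 0.575 with an estimated correlation. Monocyte markers had 0 higher, 3 lower and 5 that did not pass of 8 (0 and 3 adjusted over the list alone; camera adjusted p = 0.00258), and adjusted p = 0.19 with an estimated correlation. Of 11 stromal markers none passed alone or adjusted over the list alone, while the list was higher at camera adjusted p = 0.0309 and adjusted p = 0.638 with an estimated correlation. The number of genes that differed was 719 on log2(FPKM + 1), and it was 597 without Hif1aKO_control replicate 1, 598 without Lyz2cre_control replicate 3 and 632 without Hif1aKO_control replicate 2.

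**Figure D3:**
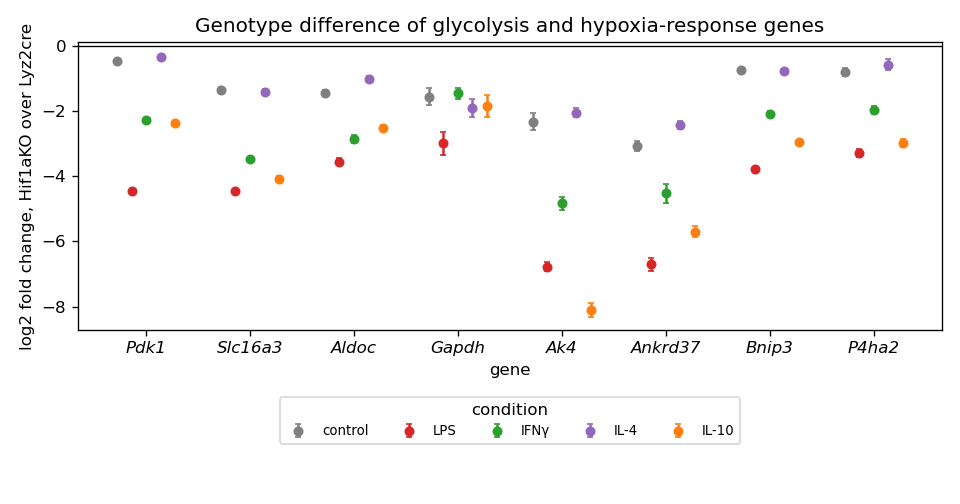
Log2 fold change between genotypes, libraries labelled Hif1aKO against Lyz2cre, of Pdk1, Slc16a3, Aldoc, Gapdh, Ak4, Ankrd37, Bnip3 and P4ha2 in 5 conditions. Points are estimates from 3 libraries a group and error bars are the approximate standard errors given in the text.

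With LPS the genotypes differed in 6654 genes, and the lists with the lowest camera p were other hypoxia-response and glycolysis genes, mostly lower in libraries labelled Hif1aKO (44 of 49 together), though the glycolysis list lost the call with an estimated correlation (adjusted p = 0.0757). Egln3, which encodes a HIF prolyl hydroxylase, stood at 0.327 ± 0.203 CPM in libraries labelled Hif1aKO and 54.8 ± 4.35 CPM in Lyz2cre (n = 3), a log2 fold change of -7.39 ± 0.15. The pyruvate dehydrogenase kinase gene Pdk1 was 22.2-fold lower (6.14 against 136 CPM), Slc16a3 22.1-fold lower (28.7 against 634 CPM) and Bnip3 13.8-fold lower (12.1 against 167 CPM). The chemokine genes Cxcl3 (-2.8 ± 0.08) and Cxcl1 (-2.47 ± 0.08), members of the NF-kB inflammatory list, which did not pass as a whole (adjusted p = 0.293), were lower, and so were Arg1 (-1.91 ± 0.07, 855 against 3220 CPM) and the inducible nitric oxide synthase gene Nos2 (-1.42 ± 0.23).

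Of 15036 genes tested with edgeR, 6654 differed, 3410 higher and 3244 lower. By the rule the highest included Rpl29 (7.65 ± 0.24), the cholesterol 25-hydroxylase gene Ch25h (2.54 ± 0.06, 59.2 against 10.2 CPM) and Draxin (2.22 ± 0.14). They also included Clic5 (2.17 ± 0.46), the heme synthesis gene Alas1 (2.12 ± 0.05, 267 against 61.4 CPM), Ripor2 (2.02 ± 0.13), Calhm6 (1.99 ± 0.15), Gdf3 (1.99 ± 0.13) and Sorl1 (1.72 ± 0.05). Clic5 rested mostly on a single library, with a standard deviation of 5.9 CPM. The lowest were Egln3, Mgarp, Ak4 (-6.78 ± 0.14), Ankrd37 (-6.71 ± 0.2), Gipr (-5.42 ± 0.28), Rgs11 (-5.09 ± 0.2), Pdk1 (-4.47 ± 0.06, adjusted p = 2.89e-18), Slc16a3, Bnip3 and Aldoc (-3.56 ± 0.11). Mgarp had 3 fragments in libraries labelled Hif1aKO and 494 in Lyz2cre, a ratio of 135 with a 95% counting interval from 45.9 to 657.

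Of 27 other hypoxia-response genes 1 was higher, 25 were lower and 1 did not pass (1 and 25 adjusted over the list alone), with a median of -1.65 and camera adjusted p = 1.42e-17. That call was kept at adjusted p = 0.000973 with an estimated correlation. Of 22 glycolysis genes 2 were higher, 19 lower and 1 did not pass (2 and 19 adjusted over the list alone; camera adjusted p = 5.21e-16), though adjusted p = 0.0757 with an estimated correlation. Together, 44 of 49 measured members of both lists were lower and 3 were higher, with a median of 3.14-fold lower. Ribosomal protein genes had 24 of 30 higher, 0 lower and 6 that did not pass (25 and 0 adjusted over the list alone; camera adjusted p = 3.36e-08). Rpl4 was higher by 0.59 ± 0.04, and the list gave adjusted p = 0.296 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 26 of 33 higher, 0 lower and 7 that did not pass (27 and 1 adjusted over the list alone; camera adjusted p = 1.03e-07). Cox5b (0.65 ± 0.08) and Sdhb (0.47 ± 0.04) were among them, and the list gave adjusted p = 0.353 with an estimated correlation.

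Cholesterol biosynthesis genes, lower in control, were higher here in 17 of 23, lower in 0, and 6 did not pass (17 and 0 adjusted over the list alone; camera adjusted p = 3.61e-05). Fdps was higher by 0.8 ± 0.08, and the list gave adjusted p = 0.261 with an estimated correlation. NRF2 antioxidant genes had 1 higher, 12 lower and 3 that did not pass of 16 (1 and 12 adjusted over the list alone; camera adjusted p = 8.98e-05). The heme oxygenase gene Hmox1 (-0.91 ± 0.07) and Slc7a11 (-0.75 ± 0.06) were lower, and the list gave adjusted p = 0.21 with an estimated correlation. Neutrophil markers had 2 higher, 11 lower and 1 that did not pass of 14 (2 and 11 adjusted over the list alone; camera adjusted p = 0.000532). Mmp9 (-1.95 ± 0.18) and Ltf (-1.3 ± 0.1) were among the lower ones, and the list gave adjusted p = 0.11 with an estimated correlation. MHC class II genes had 6 higher, 1 lower and 4 that did not pass of 11 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0229). H2-Eb1 was higher by 0.6 ± 0.08, and the list gave adjusted p = 0.465 with an estimated correlation. Cell cycle genes had 13 higher, 4 lower and 18 that did not pass of 35 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0499), and adjusted p = 0.195 with an estimated correlation. NF-kB inflammatory genes had 16 higher, 9 lower and 5 that did not pass of 30 (17 and 10 adjusted over the list alone), with a median of 0.24 but a mean of -0.04, and did not pass (adjusted p = 0.293).
With IFNγ the lists with the lowest camera p were glycolysis and other hypoxia-response genes, mostly lower in libraries labelled Hif1aKO, and type I interferon-stimulated genes, mostly higher. With an estimated correlation the glycolysis (adjusted p = 0.0554) and interferon lists (adjusted p = 0.203) lost the call. Slc16a3 stood at 20.3 ± 2.75 against 228 ± 15.5 CPM (n = 3), 11.2-fold lower, and Pdk1 at 24.2 ± 1.35 against 117 ± 7.45 CPM, 4.85-fold lower. The cytokine gene Mif was 5.5-fold lower (13.9 against 76.5 CPM) and the glycogen phosphorylase gene Pygl 4.57-fold lower (14.0 against 64.2 CPM). Ifi44 (0.78 ± 0.08), the RNA sensor gene Ddx58 (0.61 ± 0.04) and Isg15 (0.59 ± 0.06) were higher.

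Of 14987 genes tested with edgeR, 2872 differed, 1574 higher and 1298 lower. The highest by the rule included Rpl29 (8.38 ± 0.23), Atrnl1 (2.25 ± 0.07), Pcbp4 (1.74 ± 0.13), Hist1h1d (1.7 ± 0.1), Fcrls (1.7 ± 0.09), Gdf3 (1.61 ± 0.12), Hist1h4b (1.59 ± 0.14), Hist1h3e (1.57 ± 0.15) and Tma7 (1.57 ± 0.13). The lowest were Rgs11 (-5.41 ± 0.25, 0.116 against 5.07 CPM), Ak4 (-4.84 ± 0.19, 0.452 against 12.9 CPM), Slc16a3, Grhpr (-3.07 ± 0.17), Aldoc (-2.85 ± 0.12), Narf (-2.51 ± 0.05, adjusted p = 7.41e-16), Mif, Cav1 (-2.36 ± 0.19), Pdk1 and Pygl.

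Of 22 glycolysis genes 0 were higher, 18 lower and 4 did not pass (0 and 18 adjusted over the list alone; camera adjusted p = 3.47e-18). Eno1 was lower (-1.67 ± 0.09), and the list gave adjusted p = 0.0554 with an estimated correlation. Of 27 other hypoxia-response genes 0 were higher, 18 lower and 9 did not pass (0 and 18 adjusted over the list alone; camera adjusted p = 8.6e-14). Ankrd37 (-4.52 ± 0.29) and Bnip3 (-2.09 ± 0.08) were among them, and the list kept adjusted p = 0.00204 with an estimated correlation. Type I interferon-stimulated genes had 23 of 25 higher, 0 lower and 2 that did not pass (25 and 0 adjusted over the list alone; camera adjusted p = 2.89e-12). Rsad2 was higher by 0.63 ± 0.11, and the list gave adjusted p = 0.203 with an estimated correlation. NRF2 antioxidant genes had 0 higher, 9 lower and 7 that did not pass of 16 (0 and 9 adjusted over the list alone; camera adjusted p = 3.03e-06). Hmox1 (-0.94 ± 0.06) and Gclm (-0.78 ± 0.07) were lower, and the list gave adjusted p = 0.19 with an estimated correlation.

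Macrophage identity genes had 12 higher, 2 lower and 3 that did not pass of 17 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000103). Cd14 (0.75 ± 0.05) and the efferocytosis receptor gene Mertk (0.49 ± 0.04) were higher, and the list gave adjusted p = 0.0928 with an estimated correlation. Neutrophil markers had 2 higher, 6 lower and 6 that did not pass of 14 (2 and 7 adjusted over the list alone; camera adjusted p = 0.000725). Camp (-2.18 ± 0.13), Ngp (-1.68 ± 0.11) and S100a9 (-1.11 ± 0.07) were lower, and the list gave adjusted p = 0.118 with an estimated correlation. NF-kB inflammatory genes had 13 higher, 2 lower and 11 that did not pass of 26 (16 and 2 adjusted over the list alone; camera adjusted p = 0.00136). Saa3 (1.32 ± 0.09) and Ccl4 (1.08 ± 0.1) were higher, and the list gave adjusted p = 0.239 with an estimated correlation. MHC class II genes, higher in control and LPS, had 1 higher, 9 lower and 2 that did not pass of 12 (2 and 9 adjusted over the list alone; camera adjusted p = 0.00588). H2-Aa (-0.59 ± 0.05) and its activator gene Ciita (-0.49 ± 0.08) were lower, and the list gave adjusted p = 0.373 with an estimated correlation. Cell cycle genes had 5 higher, 1 lower and 29 that did not pass of 35 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00538). Mki67 was higher by 0.87 ± 0.08, and the list gave adjusted p = 0.0757 with an estimated correlation. Stromal markers had 3 higher, 0 lower and 8 that did not pass of 11 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0241, and adjusted p = 0.528 with an estimated correlation).

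With IL-4 the list with the lowest camera p was cell cycle genes, 22 of 35 higher in libraries labelled Hif1aKO with a median of 0.37, while neutrophil markers, 10 of 14 lower, differed by more (median -0.9). Of glycolysis genes 13 of 22 were lower and of other hypoxia-response genes 9 of 27, and the glycolysis list lost the call with an estimated correlation (adjusted p = 0.19). The cyclin gene Ccnd2 stood at 5.13 ± 0.833 against 1.97 ± 0.324 CPM (n = 3) and the cyclin gene Ccne2 was higher by 1.13 ± 0.2. Ankrd37 stood at 3.05 ± 0.439 against 16.5 ± 1.06 CPM, a log2 fold change of -2.44 ± 0.12, and Slc16a3 at 16.0 against 42.5 CPM (-1.41 ± 0.07). Arg1, an IL-4 target gene, was higher at 1710 against 1160 CPM (0.56 ± 0.06), and Dcstamp, needed for macrophage fusion, at 53.5 against 21.6 CPM (1.31 ± 0.14).

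Of 14967 genes tested with edgeR, 2363 differed, 1493 higher and 870 lower. The highest by the rule included Rpl29 (8.35 ± 0.2), Pilra (1.83 ± 0.11), Glb1 (1.74 ± 0.05), Atrnl1 (1.73 ± 0.1), Gdf3 (1.52 ± 0.07), Nanos1 (1.49 ± 0.11), Alas1 (1.44 ± 0.05), Dusp7 (1.4 ± 0.06) and Ccnd2 (1.38 ± 0.15). The collagen gene Col6a6 had no fragment in libraries labelled Hif1aKO and 765 in Lyz2cre, at least 253-fold lower. Others among the lowest were Slc15a2 (-3.93 ± 0.29), Ankrd37, Narf (-2.09 ± 0.05), Camp (-2.06 ± 0.1), Ak4 (-2.05 ± 0.15), Mpo (-1.89 ± 0.16), Cav1 (-1.72 ± 0.11) and Lyzl4 (-1.51 ± 0.13). The count of genes was 1410 without Hif1aKO_IL4 replicate 2.

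Cell cycle genes had 22 higher, 0 lower and 13 that did not pass of 35 (24 and 0 adjusted over the list alone; camera adjusted p = 1.72e-13), kept at adjusted p = 0.00219 with an estimated correlation. Neutrophil markers had 1 higher, 10 lower and 3 that did not pass of 14 (1 and 10 adjusted over the list alone; camera adjusted p = 9.87e-11). S100a9 was lower (-1.17 ± 0.06), and the list kept adjusted p = 0.0157 with an estimated correlation. Of 22 glycolysis genes 1 was higher, 13 lower and 8 did not pass (1 and 13 adjusted over the list alone; camera adjusted p = 2.14e-08). Pfkl was lower (-0.82 ± 0.05), and the list gave adjusted p = 0.19 with an estimated correlation. Of 27 other hypoxia-response genes 0 were higher, 9 lower and 18 did not pass (0 and 12 adjusted over the list alone; camera adjusted p = 5.31e-06). Bnip3 was lower (-0.79 ± 0.07), and the list kept adjusted p = 0.0423 with an estimated correlation. MHC class I genes had 0 higher, 7 lower and 12 that did not pass of 19 (0 and 9 adjusted over the list alone; camera adjusted p = 0.000213, and adjusted p = 0.543 with an estimated correlation). Type I interferon-stimulated genes had 0 higher, 4 lower and 21 that did not pass of 25 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00266, and adjusted p = 0.646 with an estimated correlation).

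Macrophage identity genes had 6 higher, 1 lower and 10 that did not pass of 17 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0253). Itgam was higher by 0.51 ± 0.04, and the list gave adjusted p = 0.244 with an estimated correlation. Monocyte markers had 1 higher, 2 lower and 5 that did not pass of 8 (1 and 4 adjusted over the list alone), lower at camera adjusted p = 0.0443 and adjusted p = 0.239 with an estimated correlation. IL-4-induced genes had 9 higher, 4 lower and 14 that did not pass of 27 (9 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.899), with a median of 0.01 and a mean of 0.08 where the test pointed down.
With IL-10 most glycolysis and other hypoxia-response genes were lower in libraries labelled Hif1aKO (39 of 49), while most type I interferon-stimulated, GBP and IRG GTPase and MHC class II genes were higher. With an estimated correlation these 3 lists lost the call (adjusted p from 0.0836 to 0.371). The adenylate kinase gene Ak4 stood at 0.116 ± 0.0972 against 30.7 ± 1.42 CPM (n = 3), a log2 fold change of -8.1 ± 0.21, and Egln3 at 0.277 ± 0.094 against 25.7 ± 1.73 CPM (-6.55 ± 0.15). Slc16a3 was 17.1-fold lower (21.1 against 361 CPM), the enolase gene Eno1 5.79-fold lower (46.3 against 268 CPM) and Arg1 lower by -1.25 ± 0.09. The osteopontin gene Spp1 was 3.68-fold higher (5500 against 1500 CPM), and the class II gene H2-Eb1 was higher by 0.69 ± 0.06.

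Of 14974 genes tested with edgeR, 2494 differed, 1384 higher and 1110 lower. The highest by the rule included Rpl29 (7.34 ± 0.19), Jaml (2.3 ± 0.16), Mmp25 (1.99 ± 0.18), Spp1 (1.88 ± 0.13), Gdf3 (1.71 ± 0.1), Tma7 (1.71 ± 0.13), the chemokine gene Ccl12 (1.68 ± 0.1), Glb1 (1.61 ± 0.06) and Galnt2 (1.59 ± 0.23). The lowest were Ak4, Egln3, Ankrd37 (-5.7 ± 0.17), Rgs11 (-5.0 ± 0.15), Slc16a3, P4ha2 (-2.98 ± 0.13), Bnip3 (-2.94 ± 0.06, adjusted p = 1.89e-13), Camp (-2.56 ± 0.11), Eno1 (-2.53 ± 0.09) and Aldoc (-2.52 ± 0.09).

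Of 22 glycolysis genes 0 were higher, 19 lower and 3 did not pass (0 and 19 adjusted over the list alone; camera adjusted p = 2.3e-28), kept at adjusted p = 0.0211 with an estimated correlation. Of 27 other hypoxia-response genes 1 was higher, 20 lower and 6 did not pass (1 and 22 adjusted over the list alone; camera adjusted p = 4.88e-22), kept at adjusted p = 0.000973 with an estimated correlation. Neutrophil markers had 2 higher, 10 lower and 3 that did not pass of 15 (2 and 11 adjusted over the list alone; camera adjusted p = 5.06e-10). Mmp9 (-1.7 ± 0.09) and Ngp (-1.7 ± 0.09) were lower, and the list kept adjusted p = 0.0362 with an estimated correlation. Type I interferon-stimulated genes had 17 higher, 0 lower and 8 that did not pass of 25 (21 and 0 adjusted over the list alone; camera adjusted p = 7.72e-11). Ifi44 (1.29 ± 0.17) and Ifit2 (1.2 ± 0.13) were higher, and the list gave adjusted p = 0.19 with an estimated correlation.

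GBP and IRG GTPase genes had 10 higher, 0 lower and 5 that did not pass of 15 (13 and 0 adjusted over the list alone; camera adjusted p = 2.29e-07). Gbp5 (1.46 ± 0.27) and Gbp3 (0.84 ± 0.07) were higher, and the list gave adjusted p = 0.0836 with an estimated correlation. Cholesterol biosynthesis genes had 17 higher, 0 lower and 6 that did not pass of 23 (18 and 0 adjusted over the list alone; camera adjusted p = 6.54e-10). Dhcr7 was higher by 0.74 ± 0.13, and the list gave adjusted p = 0.051 with an estimated correlation. MHC class II genes had 8 higher, 0 lower and 3 that did not pass of 11 (8 and 0 adjusted over the list alone; camera adjusted p = 0.000905, and adjusted p = 0.371 with an estimated correlation). MHC class I genes had 4 higher, 2 lower and 13 that did not pass of 19 (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.862). NRF2 antioxidant genes had 0 higher, 7 lower and 9 that did not pass of 16 (0 and 7 adjusted over the list alone; camera adjusted p = 0.00444, and adjusted p = 0.244 with an estimated correlation).

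Arginine and nitric oxide genes had 0 higher, 4 lower and 6 that did not pass of 10 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00723, and adjusted p = 0.166 with an estimated correlation). Erythroid and megakaryocyte markers had 0 higher, 3 lower and 1 that did not pass of 4 (1 and 3 adjusted over the list alone; camera adjusted p = 0.0221). The platelet factor gene Pf4 was lower (-1.04 ± 0.06), and the list gave adjusted p = 0.228 with an estimated correlation. Stromal markers had 0 higher, 2 lower and 9 that did not pass of 11 (0 and 2 adjusted over the list alone; lower at camera adjusted p = 0.013, and adjusted p = 0.564 with an estimated correlation).

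**Figure D4:**
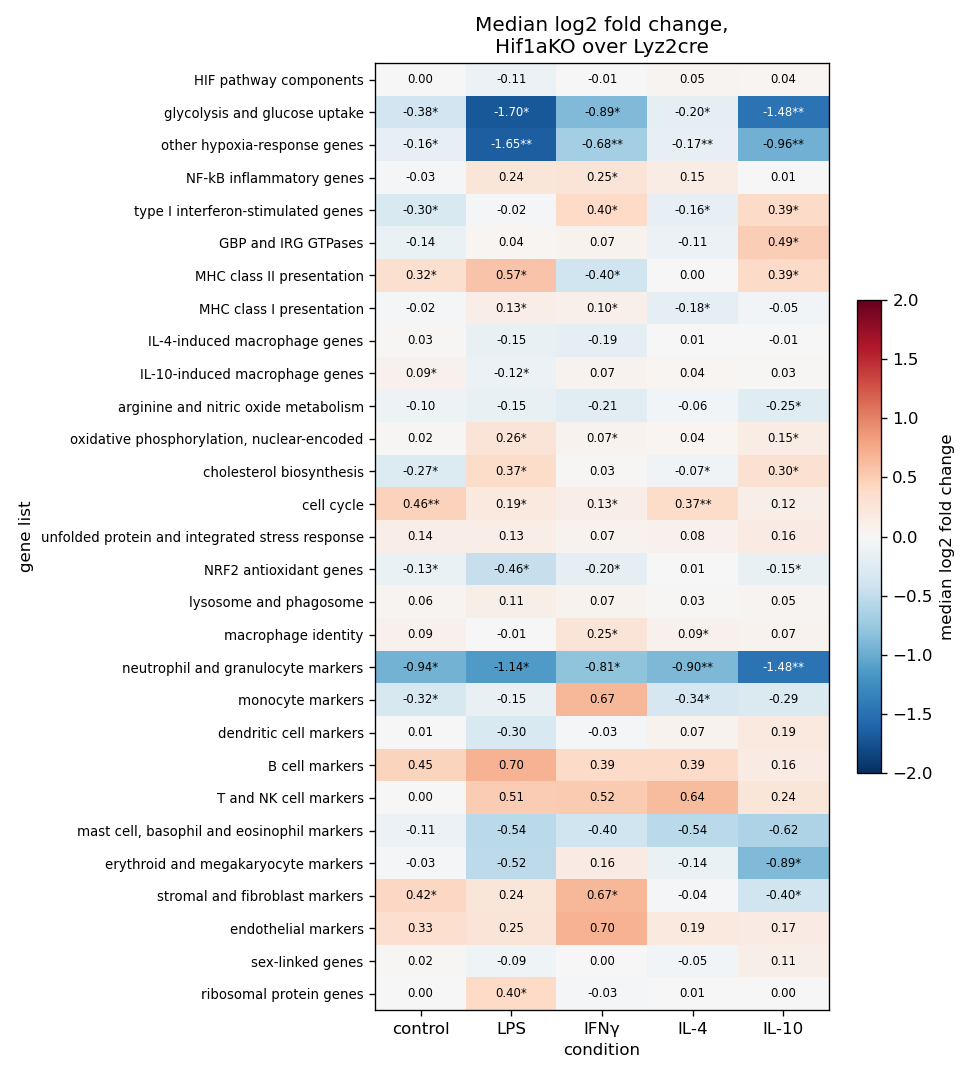
Median log2 fold change between genotypes of each gene list (lines) in 5 conditions (columns), libraries labelled Hif1aKO against Lyz2cre, 3 libraries a group, colours from -2 to 2. A single star marks camera adjusted p under 0.05 and a double star one that is also under 0.05 with an estimated correlation.

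Across the 5 conditions, 133 genes were higher and 130 lower in libraries labelled Hif1aKO every time, of 14420 genes tested in all. Independent calls would give 0.146 and 0.0387, but the fits share control libraries and perhaps mice. Genes lower in all 5 conditions included Slc16a3, Aldoc, Pdk1, Bnip3, Ak4, Ankrd37, Mif, Narf, Rgs11, Egln3 and Camp. Capn11 (ENSMUSG00000058626, chromosome 17, 45630204 to 45659325) had no fragment in libraries labelled Hif1aKO and 235 in Lyz2cre in control, 108 in LPS, 75 in IFNγ, 171 in IL4 and 163 in IL10, at least 70.3-fold, 29.5-fold, 20.4-fold, 56.5-fold and 59.3-fold lower. Rpl29 (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568) was highest by the median over conditions, and Il2rb, which encodes a receptor chain for IL-2 and IL-15, was higher by 2.94, 1.75, 2.03, 2.36 and 1.52 in the same order. The neutrophil marker list was lower in all 5 genotype comparisons, in 2 of them also with an estimated correlation. At least 3 conditions shared 756 higher and 595 lower genes, and 812 genes were higher in some condition and lower in another. Of 259 windows of 10 Mb, 2 neighbouring ones on chromosome 9 held more called genes than others (adjusted p = 0.00302 and 0.00516), with 44 of 190 genes called. Another crowded window lay on chromosome 13, where all 35 called genes were higher, 30 of them histone genes (adjusted p = 1.2e-16). Over all histone genes 36 were higher and 0 lower in control, 34 and 4 in LPS, 40 and 0 in IFNγ, 35 and 0 in IL4, and 9 and 0 in IL10, a group chosen after its values were seen.

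**Figure D5:**
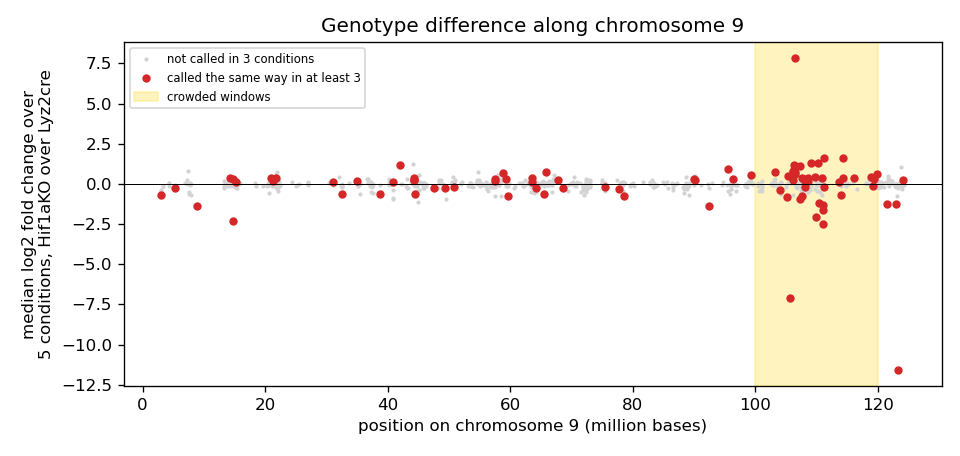
Genes along chromosome 9, with position on the horizontal axis and the median over 5 conditions of the log2 fold change between genotypes on the vertical axis. The shaded part runs from 100 to 120 Mb.

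LPS in Lyz2cre macrophages raised every measured NF-kB inflammatory gene and lowered most cell cycle and cholesterol biosynthesis genes, the last at adjusted p = 0.294 with an estimated correlation. Nos2 went from 0.0399 ± 0.0402 to 575 ± 39.7 CPM (n = 3), a log2 fold change of 13.6 ± 0.56, and Cxcl3 from 0.125 to 321 CPM (11.15 ± 0.16). Arg1 rose from 2.42 to 3220 CPM (10.36 ± 0.11), and the glycolysis regulator gene Pfkfb3 from 37.8 to 1500 CPM (5.31 ± 0.05). The resident macrophage gene Gpr34 had 2298 fragments in control and 2 with LPS, a ratio of 1140 (95% counting interval 316 to 9450).

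With edgeR 10264 genes changed, 5158 up and 5106 down, and in libraries labelled Hif1aKO 10663 changed, 5405 up and 5258 down. The largest rises by the rule were Nos2, Csf3, Saa1, U90926, Cxcl3, the complement gene Cfb (11.11 ± 0.12), Stfa3, Ccl5 (10.73 ± 0.13), Il1f6 and Gipr. Control libraries held no fragment of Csf3 (at least 631-fold higher with LPS), Saa1 (409), Stfa3 (237), Il1f6 (195) or Gipr (180), and 2 fragments of U90926 (ratio 2860, 791 to 23600). The largest falls were Gpr34, Pde1c (1 fragment with LPS, ratio 607, 108 to 24000), the prostaglandin-degrading gene Hpgd (-8.64 ± 0.18), Zbtb16 (2 fragments, ratio 348, 95.9 to 2880), Rasgrp3 (-8.07 ± 0.11), Nptx1 (3 fragments, ratio 273, 93 to 1330), Slco2b1 (-7.38 ± 0.17), Lama3 (-6.89 ± 0.23), Abca6 (-6.67 ± 0.31) and Col4a5 (-6.4 ± 0.12).

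NF-kB inflammatory genes rose in 30 of 30, and in 30 adjusted over the list alone (camera adjusted p = 1.79e-15), kept at adjusted p = 0.0236 with an estimated correlation. Interferon-stimulated genes rose in 25 of 25 (25 adjusted over the list alone; camera adjusted p = 1e-14, and adjusted p = 0.203 with an estimated correlation). MHC class I genes rose in 19 of 19 (19 adjusted over the list alone; camera adjusted p = 1.8e-10, and adjusted p = 0.21 with an estimated correlation). Of glycolysis genes 18 rose, 2 fell and 2 did not pass (18 and 2 adjusted over the list alone; camera adjusted p = 7.58e-08, and adjusted p = 0.207 with an estimated correlation). Of other hypoxia-response genes 16 rose, 8 fell and 3 did not pass (16 and 8 adjusted over the list alone; camera adjusted p = 0.0413, and adjusted p = 0.19 with an estimated correlation). Of unfolded protein genes 18 rose, 1 fell and 1 did not pass (18 and 1 adjusted over the list alone; camera adjusted p = 1.02e-06, and adjusted p = 0.0928 with an estimated correlation). Of arginine and nitric oxide genes 8 rose, 1 fell and 1 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 0.000448, and adjusted p = 0.0554 with an estimated correlation).

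Cell cycle genes fell in 30 of 35, 1 rose and 4 did not pass (30 and 1 adjusted over the list alone; camera adjusted p = 8.45e-07), kept at adjusted p = 0.0157 with an estimated correlation. Ribosomal protein genes fell in 27 of 30, 1 rose and 2 did not pass (27 and 1 adjusted over the list alone; camera adjusted p = 8.37e-06, and adjusted p = 0.403 with an estimated correlation). Cholesterol biosynthesis genes fell in 16 of 23, 2 rose and 5 did not pass (16 and 2 adjusted over the list alone; camera adjusted p = 0.000102, and adjusted p = 0.294 with an estimated correlation).
IFNγ in Lyz2cre macrophages raised all measured members of the GBP and IRG GTPase, type I interferon-stimulated, MHC class I and oxidative phosphorylation lists, of which the GTPases rose by most (median 7.25). With an estimated correlation the GTPase list kept the call, while the interferon (adjusted p = 0.191), MHC class I (adjusted p = 0.156) and oxidative phosphorylation lists (adjusted p = 0.207) lost it. The chemokine gene Cxcl9 went from 0.303 ± 0.0929 to 8570 ± 347 CPM (n = 3), a log2 fold change of 14.79 ± 0.17, and Gbp4 from 0.211 to 2390 CPM (13.41 ± 0.16). Nos2 rose from 0.0389 to 643 CPM (13.79 ± 0.19) and the class II activator gene Ciita from 12.7 to 593 CPM (5.57 ± 0.11). The mannose receptor gene Mrc1 fell from 632 to 26.5 CPM (-4.57 ± 0.08) and the costimulatory receptor gene Cd28 from 76.4 to 0.217 CPM (-8.36 ± 0.11).

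With edgeR 10865 genes changed, 5354 up and 5511 down, and in libraries labelled Hif1aKO 11164 changed, 5360 up and 5804 down. Rises by the rule were Gbp2b (2 fragments in control, ratio 51300, 14200 to 423000), Cxcl9, Gbp10 (at least 2110-fold), Nos2, Gbp4, Serpina3f (12.72 ± 0.1), Serpina3g (12.65 ± 0.1), Cxcl11 (1 fragment, ratio 5820, 1050 to 230000), Clic5 (11.66 ± 0.12) and Gbp11 (at least 439-fold). Falls were Nptx1 (at least 271-fold), Abca6 (at least 214-fold), Lama3 (2 fragments with IFNγ, ratio 778, 215 to 6430), Dkk2 (-8.86 ± 0.26), Pde1c (1 fragment, ratio 602, 108 to 23800), Htr2b (-8.67 ± 0.26), Slco2b1 (-8.58 ± 0.25), Cd28, Gpr183 (-7.52 ± 0.22) and Hpgd (-6.99 ± 0.15).

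GBP and IRG GTPase genes rose in 14 of 14, with 14 adjusted over the list alone (camera adjusted p = 3.82e-11), kept at adjusted p = 0.0412 with an estimated correlation. Type I interferon-stimulated genes rose in 25 of 25 (25 adjusted over the list alone; camera adjusted p = 1.98e-13, and adjusted p = 0.191 with an estimated correlation). MHC class I genes rose in 19 of 19 (19 adjusted over the list alone; camera adjusted p = 2.89e-12, and adjusted p = 0.156 with an estimated correlation). MHC class II genes rose in 11 of 12 and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 6.92e-06, and adjusted p = 0.19 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 33 of 33 (33 adjusted over the list alone; camera adjusted p = 2.29e-11, and adjusted p = 0.207 with an estimated correlation). Of glycolysis genes 19 rose and 3 fell (19 and 3 adjusted over the list alone; camera adjusted p = 3.03e-06, and adjusted p = 0.239 with an estimated correlation). Of NF-kB inflammatory genes 18 rose, 6 fell and 2 did not pass (18 and 6 adjusted over the list alone; camera adjusted p = 0.000556, and adjusted p = 0.222 with an estimated correlation). Cholesterol biosynthesis genes fell in 18 of 23, 2 rose and 3 did not pass (18 and 2 adjusted over the list alone; camera adjusted p = 0.000254, and adjusted p = 0.0928 with an estimated correlation).
IL-4 in Lyz2cre macrophages raised all measured members of the IL-4-induced list. Retnla had no fragment in control and 220766 with IL-4 (at least 76100-fold, n = 3), Arg1 went from 2.55 ± 0.513 to 1160 ± 73.1 CPM (8.81 ± 0.09), and Chil3 rose by 3.73 ± 0.04. The fractalkine receptor gene Cx3cr1 fell from 13.5 to 0.622 CPM (-4.44 ± 0.14) and Il1b from 8.01 to 0.529 CPM (-3.92 ± 0.28). With edgeR 7782 genes changed, 3846 up and 3936 down, and in libraries labelled Hif1aKO 8013 changed, 4122 up and 3891 down. Other rises by the rule were Rnase2a (at least 3590-fold), Scn3a (2 fragments in control, ratio 2500, 691 to 20600), Il31ra (1 fragment, ratio 1100, 196 to 43400), Mgl2 (9.1 ± 0.16), Pdcd1lg2 (7.72 ± 0.15), Kcnd3 (7.12 ± 0.3), Flt1 (6.96 ± 0.12) and Ocstamp (6.52 ± 0.14). Other falls were Adgre4 (-3.71 ± 0.16), Clec4n (-3.7 ± 0.1), Ifit3b (-3.62 ± 0.2), Cd300e (-3.43 ± 0.23), Gpr162 (-3.36 ± 0.15), Icosl (-3.33 ± 0.12), Pilrb2 (-3.23 ± 0.22) and Nfkbiz (-3.09 ± 0.07). IL-4-induced genes rose in 27 of 27, with 27 adjusted over the list alone (camera adjusted p = 1.22e-22), kept at adjusted p = 0.013 with an estimated correlation. Oxidative phosphorylation genes rose in 32 of 33, 0 fell and 1 did not pass (32 and 0 adjusted over the list alone; camera adjusted p = 1.39e-11, and adjusted p = 0.193 with an estimated correlation). Of MHC class II genes 9 rose, 0 fell and 2 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 4.42e-05, and adjusted p = 0.239 with an estimated correlation). Interferon-stimulated genes fell in 20 of 25, 2 rose and 3 did not pass (22 and 2 adjusted over the list alone; camera adjusted p = 0.000188, and adjusted p = 0.577 with an estimated correlation).

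IL-10 in Lyz2cre macrophages raised all measured cholesterol biosynthesis genes and most glycolysis genes, the last at adjusted p = 0.137 with an estimated correlation. The cytokine signalling inhibitor gene Socs3 went from 3.84 ± 0.679 to 589 ± 13.5 CPM (7.25 ± 0.1, n = 3), Arg1 from 2.54 to 333 CPM (7.02 ± 0.13), the chemokine gene Ccl5 from 0.82 to 184 CPM (7.84 ± 0.22) and Slc16a3 from 53.8 to 361 CPM (2.75 ± 0.08). Rnf144b fell from 82.8 to 3.18 CPM (-4.7 ± 0.09). With edgeR 7469 genes changed, 3677 up and 3792 down, and in libraries labelled Hif1aKO 7932 changed, 3982 up and 3950 down. Other rises by the rule were Nrg1 (9.04 ± 0.25), Cd38 (7.6 ± 0.13), Cfb (7.22 ± 0.17), Gja1 (7.05 ± 0.14), Steap4 (6.98 ± 0.28), Ccl12 (6.89 ± 0.2) and Mmp14 (6.62 ± 0.12). Other falls were Nptx1 (2 fragments with IL-10, ratio 387, 107 to 3200), Dcstamp (-6.8 ± 0.5), Pde1c (-5.41 ± 0.24), Chst3 (-5.0 ± 0.28), Serpinb6b (-4.99 ± 0.27), Hpgd (-4.49 ± 0.12), Rasgrp3 (-4.46 ± 0.1), Angptl4 (-4.3 ± 0.23) and Lama3 (-4.15 ± 0.15). Cholesterol biosynthesis genes rose in 23 of 23, with 23 adjusted over the list alone (camera adjusted p = 1.83e-11), kept at adjusted p = 0.0366 with an estimated correlation. Of glycolysis genes 18 rose, 1 fell and 3 did not pass (18 and 1 adjusted over the list alone; camera adjusted p = 4.8e-10, and adjusted p = 0.137 with an estimated correlation). Of IL-10-induced genes 16 rose, 3 fell and 2 did not pass (16 and 3 adjusted over the list alone; camera adjusted p = 3.6e-09, and adjusted p = 0.0937 with an estimated correlation). IL-4-induced genes fell in 14 of 23, 3 rose and 6 did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.166 with an estimated correlation).
Responses to LPS differed between the genotypes for 3793 genes with edgeR, 1827 with a larger rise or smaller fall in libraries labelled Hif1aKO (called above here and for the other stimuli) and 1966 the other way (below). Pdk1 went from 67.1 ± 3.29 to 136 ± 4.52 CPM in Lyz2cre and from 49.0 ± 1.55 to 6.14 ± 0.299 CPM in libraries labelled Hif1aKO (n = 3), a difference in log2 response of -4.02 ± 0.08. Egln3 went from 3.84 to 54.8 CPM against 1.64 to 0.327 CPM (-6.17 ± 0.27), Ak4 from 2.04 to 46.0 CPM against 0.414 to 0.416 CPM (-4.44 ± 0.37), and Arg1 from 2.42 to 3220 CPM against 12.7 to 855 CPM (-4.28 ± 0.14). Above were Ch25h, from 0.326 to 10.2 CPM against 0.458 to 59.2 CPM (2.05 ± 0.25), Wfdc21 (2.53 ± 0.29), Cables1 (2.41 ± 0.61), Ripor2 (2.29 ± 0.23) and the receptor gene Trem3 (2.22 ± 0.31). Gipr (-7.33 ± 2.23) had no fragment in Lyz2cre controls, so its size depends on the prior count of the fit. Its call was lost without Hif1aKO_control replicate 1. Cables1 took the other sign on log2(FPKM + 1) (-0.13) and its call was lost there. Other hypoxia-response genes had 25 below, 1 above and 1 that did not pass of 27 (25 and 1 adjusted over the list alone; camera adjusted p = 7.43e-20), kept at adjusted p = 0.000973 with an estimated correlation. Glycolysis genes had 17 below, 1 above and 4 that did not pass of 22 (18 and 1 adjusted over the list alone; camera adjusted p = 1.62e-16, and adjusted p = 0.0721 with an estimated correlation). Cholesterol biosynthesis genes, with a median of -0.25 in libraries labelled Hif1aKO and -0.86 in Lyz2cre, had 19 above, 0 below and 4 that did not pass of 23 (20 and 0 adjusted over the list alone; camera adjusted p = 3.06e-11, and adjusted p = 0.112 with an estimated correlation).

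Responses to IFNγ differed for 786 genes with edgeR, 370 up and 416 down. The myeloid gene Plac8 went from 1.45 ± 0.352 to 33.7 ± 2.98 CPM in Lyz2cre and from 0.576 ± 0.114 to 56.3 ± 0.735 CPM in libraries labelled Hif1aKO (n = 3), a difference of 2.13 ± 0.24. Saa3 (1.78 ± 0.27), Ms4a4c (1.74 ± 0.23), Ms4a4a (2.37 ± 0.43) and Lhx2 (2.19 ± 0.54) were also above. Ak4 went from 1.99 to 12.9 CPM against 0.404 to 0.452 CPM (-2.51 ± 0.37), Rgs11 from 6.68 to 5.07 CPM against 1.92 to 0.116 CPM (-3.6 ± 0.34), and Arg1 from 2.36 to 5.19 CPM against 12.4 to 3.08 CPM (-3.15 ± 0.22). Cmbl (-2.85 ± 0.63) and Slc15a2 (-2.41 ± 0.59) were below as well. Calls were lost for Lhx2 without any 1 of 3 libraries and for Cmbl on FPKM values, and Slc15a2 took the other sign on log2(FPKM + 1) (0.13). Interferon-stimulated genes had 23 above, 0 below and 2 that did not pass of 25 (25 and 0 adjusted over the list alone; camera adjusted p = 7.35e-27, and adjusted p = 0.0689 with an estimated correlation). Other hypoxia-response genes, with a median of -0.76 in libraries labelled Hif1aKO and -0.26 in Lyz2cre, had 14 below, 0 above and 13 that did not pass of 27 (17 and 0 adjusted over the list alone; camera adjusted p = 2.04e-12), kept at adjusted p = 0.00219 with an estimated correlation. Cholesterol biosynthesis genes, with a median of -0.48 in libraries labelled Hif1aKO and -0.78 in Lyz2cre, had 5 above, 0 below and 18 that did not pass of 23 (15 and 0 adjusted over the list alone; camera adjusted p = 1.7e-08), kept at adjusted p = 0.0229 with an estimated correlation.

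Responses to IL-4 differed for 144 genes with edgeR, 100 up and 44 down. The chemokine gene Ccl7 went from 0.49 ± 0.169 to 23.3 ± 1.76 CPM in Lyz2cre and from 1.85 ± 0.212 to 16.4 ± 1.4 CPM in libraries labelled Hif1aKO (n = 3), a difference of -2.41 ± 0.24. Arg1 went from 2.55 to 1160 CPM against 13.3 to 1710 CPM (-1.81 ± 0.13), so its higher level with IL-4 went together with a smaller rise. Ccl2 (-1.33 ± 0.19), Itgax (-0.91 ± 0.1) and the inhibitory Fc receptor gene Fcgr2b (-0.85 ± 0.06) also had smaller rises. Dusp5 (1.43 ± 0.13), Dcstamp (1.26 ± 0.24), Cass4 (1.18 ± 0.27), Pilra (1.1 ± 0.14) and Il18rap (1.08 ± 0.21) were above. On FPKM values the calls of Dcstamp, Cass4, Il18rap, Pilra and Ccl2 were lost in at least 1 of the 2 tests, and that of Cass4 also with RLE size factors (adjusted p = 0.0577). Cholesterol biosynthesis genes had 3 above, 0 below and 20 that did not pass of 23 (10 and 0 adjusted over the list alone; camera adjusted p = 1.12e-05, and adjusted p = 0.191 with an estimated correlation). The count was 233 with DESeq2, 138 up and 95 down, 447 without a filter on low counts, 73 on log2(FPKM + 1), 63 on log2(FPKM + 0.1) and 78 without Hif1aKO_IL4 replicate 2.

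Responses to IL-10 differed for 611 genes with edgeR, 260 up and 351 down. Slc16a3 went from 53.8 ± 4.97 to 361 ± 23.4 CPM in Lyz2cre and stood at 21.1 CPM both without and with IL-10 in libraries labelled Hif1aKO (n = 3), a difference of -2.75 ± 0.12. Ak4 (-5.75 ± 0.47), Egln3 (-5.33 ± 0.22), Arg1 (-3.61 ± 0.16, from 2.54 to 333 CPM against 13.3 to 141 CPM) and Rgs11 (-3.19 ± 0.21) were below. The interferon-induced genes Ifit3b (1.72 ± 0.18), Ifit2 (1.66 ± 0.18) and Ifi44 (1.39 ± 0.25) were above, with Galnt2 (1.56 ± 0.35) and Ms4a4c (1.51 ± 0.28), and the call of Galnt2 was lost on log2(FPKM + 0.1). Glycolysis genes had 18 below, 0 above and 4 that did not pass of 22 (18 and 0 adjusted over the list alone; camera adjusted p = 1.32e-28), kept at adjusted p = 0.0211 with an estimated correlation. Other hypoxia-response genes had 16 below, 1 above and 10 that did not pass of 27 (22 and 1 adjusted over the list alone; camera adjusted p = 1.58e-24), kept at adjusted p = 0.000973 with an estimated correlation. Cholesterol biosynthesis genes had 15 above, 0 below and 8 that did not pass of 23 (21 and 0 adjusted over the list alone; camera adjusted p = 3.17e-22), kept at adjusted p = 0.0106 with an estimated correlation. Cell cycle genes, with a median of -0.61 in libraries labelled Hif1aKO and -0.33 in Lyz2cre, had 2 below, 0 above and 33 that did not pass of 35 (3 and 0 adjusted over the list alone; camera adjusted p = 1.03e-05), kept at adjusted p = 0.0236 with an estimated correlation. Interferon-stimulated genes had 21 above, 0 below and 4 that did not pass of 25 (24 and 0 adjusted over the list alone; camera adjusted p = 2.66e-23, and adjusted p = 0.0554 with an estimated correlation). The count was 972 without Hif1aKO_IL10 replicate 3, 396 without Lyz2cre_IL10 replicate 1, 944 in a single fit of all 30 libraries and 1175 without a filter on low counts.
The camera test of genotypes in control did not pass for dendritic cell (adjusted p = 0.79), mast cell (0.887), erythroid (0.893), endothelial (0.512), lysosome (0.0925), unfolded protein (0.0867) or sex-linked genes (0.76). The endothelial list had a median of 0.33 and a mean of 0.24 where the test pointed down. The unfolded protein list had a median of 0.14 and a mean of -0.01, and its test did not pass in any genotype comparison. Mitochondrially encoded genes had 15 of 28 members in the tables and 0 past the filter. B cell markers had 3 and T and NK cell markers 2 past it in all tables, too few for a test in control; with IFNγ neither list passed (adjusted p = 0.309 and 0.579). All groups had 0 to 4 fragments of the female-specific gene Xist in each library and between 125 and 207 CPM of the Y-linked gene Ddx3y.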

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

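The tests of crowding on chromosome 9, of its chromosome segments and response, of a window around Hif1a, and of exchanged labels and undeleted exons were chosen only after the results were seen, and so was sorting other splits by genotype. The share of shared genes on the Hif1a chromosome, the sex of the mice, other cell types and other splits were set as tests before. Results in the next paragraph stand here because the edgeR test of the difference between the genotypes' responses to the same stimulus passed.

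For LPS this covered 3793 genes, among them Hif1a (0.65), Wfdc21 (2.53), Cables1 (2.41), Ripor2 (2.29), Trem3 (2.22), Ch25h (2.05), Gipr (-7.33), Egln3 (-6.17), Ak4 (-4.44), Arg1 (-4.28) and Pdk1 (-4.02), and the other hypoxia-response list (7.43e-20 as camera adjusted p, also for the lists that follow). For IFNγ it covered 786 genes, among them Ms4a4a (2.37), Lhx2 (2.19), Plac8 (2.13), Saa3 (1.78), Ms4a4c (1.74), Rgs11 (-3.6), Arg1 (-3.15), Cmbl (-2.85), Ak4 (-2.51) and Slc15a2 (-2.41), with the other hypoxia-response (2.04e-12) and cholesterol biosynthesis lists (1.7e-08). For IL-4 it covered 144 genes, among them Dusp5 (1.43), Dcstamp (1.26), Cass4 (1.18), Pilra (1.1), Il18rap (1.08), Ccl7 (-2.41), Arg1 (-1.81), Ccl2 (-1.33), Itgax (-0.91) and Fcgr2b (-0.85). For IL-10 it covered 611 genes, among them Hif1a (0.45), Ifit3b (1.72), Ifit2 (1.66), Galnt2 (1.56), Ms4a4c (1.51), Ifi44 (1.39), Ak4 (-5.75), Egln3 (-5.33), Arg1 (-3.61), Rgs11 (-3.19) and Slc16a3 (-2.75). Lists for IL-10 were glycolysis (1.32e-28), other hypoxia-response (1.58e-24), cholesterol biosynthesis (3.17e-22) and cell cycle genes (1.03e-05).

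Other splits of the libraries of an interaction, drawn 100 times, do not decide whether chance can be excluded. For LPS 7 splits, the real one included, called at least 3793 genes and another called up to 5588. For IFNγ 8 splits called at least 786 genes (highest other 3130), for IL-4 6 called at least 144 (3375) and for IL-10 9 called at least 611 (2597). The median of the other splits was 0 genes for each stimulus. All other splits that reached the real count gave a group different numbers of libraries labelled Hif1aKO with and without the stimulus, and 5 of 6 for LPS, 7 of 7 for IFNγ, 5 of 5 for IL-4 and 7 of 8 for IL-10 had opposite majorities. Such splits turn a genotype difference present in both conditions into an interaction by construction. For each comparison of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split alone reached its count in each of the 13 comparisons (1 of 10), and the highest other count was 2, for the genotypes in IL4, and 0 elsewhere.

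Of genotype differences shared by all conditions, passenger genes around the floxed locus cannot be told apart as an explanation: 4.6% of genes called in at least 3 conditions lay on chromosome 12 against 3.17% of all tested genes, a ratio of 1.45, between the bounds set before (at most 1.2 against, over 2 for); within 20 Mb of Hif1a the share called was 1.01 times that of all genes (interval 0.61 to 1.55), but between 90000001 and 100000000 it was 7 of 20 genes (adjusted p = 0.0743). A difference in the sex of the mice was argued against by Y-linked genes, which differed by at most 0.4. Marker lists of other marrow cell types moved the same way in at least 3 conditions for 1 list, neutrophil markers, lower in 5 but with an estimated correlation in only 2, so a smaller share of granulocyte RNA in libraries labelled Hif1aKO may account for that part. Monocyte markers were lower in 2, stromal markers higher in 2 and lower in 1 and erythroid markers lower in 1, each in 0 with an estimated correlation. Besides passengers, the deletion itself and untested differences between the mice stay open.

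Called genes crowded on chromosome 9 between 100000001 and 120000000, 30 higher and 14 lower, of which 3 are granulocyte markers. If segments of that chromosome differed between the mice, differences should be alike in all conditions, and their median relative spread was 0.647 times that of other called genes (0.393 against 0.608; share of 10000 draws 1e-04, the smallest these can give), so such segments are a candidate explanation. A response to the deletion by these genes cannot be told apart: 38.6% of them were called for the interaction with LPS (interval 24.4 to 54.5), against 48.4% of other called genes and 89.8% of glycolysis and hypoxia-response genes.

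Libraries labelled Hif1aKO had higher Hif1a levels in CPM. Exchanged genotype labels were argued against, since only 6.12% of measured glycolysis and hypoxia-response genes were higher in libraries labelled Hif1aKO with LPS. Fragments from exons that were not deleted could give the log2 fold change of 0.91 in LPS, but cannot be told apart from an intact gene because gene totals do not say where in the gene fragments lie.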

How the results depend on the processing

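The tests without the libraries that stood apart and with genes of status other than OK kept in the lists were chosen only after the results were seen. Of 1238 gene results 1018 kept their direction and their side of the threshold under every alternative, and of 20383 alternative values 19279 did; of 479 list results 162 did. Depth limits what can be said of genes with few fragments. No scaling moved the median log2 fold change of all genes by more than 0.03. Where not said otherwise, the cause was not tested.

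The sign turned for Cables1 in the interaction with LPS (-0.13) and for Slc15a2 in that with IFNγ (0.13), both on log2(FPKM + 1) with limma-trend.

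Counting only changes of at least 2-fold leaves fewer genes by construction: 172 for the genotypes in control, 894 in LPS, 384 in IFNγ, 216 in IL4 and 349 in IL10. In Lyz2cre it leaves 3432 for LPS, 4025 for IFNγ, 1390 for IL4 and 1859 for IL10, in libraries labelled Hif1aKO 3717, 4464, 1323 and 2060, and for the interactions 508, 108, 25 and 126 in the same order. With limma-trend the genotypes in control differed in 719 genes on log2(FPKM + 1) and in 713 on log2(FPKM + 0.1), and the interaction with IL4 in 73 and 63. That interaction counted 447 without a filter on low counts and 233 with DESeq2 (138 up, 95 down, where 100 and 44 were counted with edgeR). The interaction with IL10 counted 1175 without a filter, 944 in a single fit of all 30 libraries and 1011 without the libraries that stood apart.

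With a library left out, counts ran from 597 (without Hif1aKO_control replicate 1) to 1251 (without Hif1aKO_control replicate 3) for the genotypes in control, where 598 were left without Lyz2cre_control replicate 3 and 632 without Hif1aKO_control replicate 2. For the genotypes in IL4 they ran from 1410 (without Hif1aKO_IL4 replicate 2) to 1810 (without Hif1aKO_IL4 replicate 3). For the interaction with IL4 they ran from 78 (without Hif1aKO_IL4 replicate 2) to 170 (without Lyz2cre_control replicate 1), with 84 without Lyz2cre_control replicate 3, 86 without Lyz2cre_IL4 replicate 1 and 90 without Hif1aKO_IL4 replicate 1. For the interaction with IL10 they ran from 396 (without Lyz2cre_IL10 replicate 1) to 972 (without Hif1aKO_IL10 replicate 3). In other comparisons no library moved the count by more than 1.5 times, as for the genotypes in LPS (5552 to 6263) and IFNγ (2098 to 2777).

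Of 479 list tests 186 passed at the preset correlation, 26 with a correlation estimated per list, 323 with fry and 188 with genes of status other than OK kept.

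Replicate numbers do not pair libraries per the labels, and as a block they moved no count by more than 1.5 times: 1327 genes for the genotypes in control and 3223 in IFNγ. With the block 1217 gene results kept their side and 21 did not, and 184 list tests passed. By residual correlation 12 of 30 libraries lay closest to one of their own number, where about 1 in 3 would by chance, so the data give no hint of pairing.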

Other observations

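The choice of histone genes as a group was made only after the results were seen. Histone genes, which are transcribed mostly during DNA replication, were not tested as a set. In Lyz2cre macrophages 24 of 49 fell and 3 rose with LPS and 35 fell and 2 rose with IFNγ, while 25 of 52 rose with IL-4 and 16 of 50 rose with IL-10, where 2 fell. Their median log2 fold change between genotypes was 0.88 in control, 1.05 in LPS, 1.27 in IFNγ, 0.65 in IL4 and 0.27 in IL10. The log2 response to IL-10 was lower in libraries labelled Hif1aKO than in Lyz2cre for 15 of 50 and higher for 0.

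Lyz2, whose promoter drives the Cre recombinase in both genotypes, was counted at 52.7 ± 0.513 CPM in Lyz2cre controls and 37.5 ± 1.5 CPM in controls labelled Hif1aKO, at 111 ± 4.73 against 90.2 ± 2.73 CPM with LPS, 17.1 ± 0.361 against 10.4 ± 0.97 CPM with IL-4 and 62.2 ± 4.38 against 39.6 ± 3.97 CPM with IL-10. With IFNγ it stood the other way, at 22.7 ± 1.87 against 27.1 ± 0.153 CPM. The neutrophil marker list had a median of -0.81 between genotypes with IFNγ, or -0.63 with groups of no fragments set to 3.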
